A study of Mus musculus with 12 samples.

How the data were processed

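Gene expression was measured on 12 one-colour Illumina mouse bead arrays hybridised with biotin-labelled cRNA from E14 cells, a male embryonic stem (ES) cell line of strain 129/Ola. The cells were grown without feeders on gelatin in medium with fetal calf serum. The design varied genotype: wild type cells at day 0, and cells at day 4 after 4-hydroxytamoxifen (OHT) had activated a Cre recombinase fused to the estrogen receptor (CreER), which removed both alleles of Hdac1 and 1 allele of Hdac2. These are called deleted cells. The other factor was culture, with leukaemia inhibitory factor (LIF) or for 4 days without it. Per the labels OHT was given for 16 h at 1 uM, and the OHT label stands on all 12 samples, wild type included. Genotype and day were therefore the same division of the samples, and no value separates them. Each of the 4 groups had 3 arrays. Nothing in the labels says whether the arrays of a group came from separate cultures, so the p-values may measure technical spread only.

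The deposited files held 2 tables of 45281 probes. The non-normalized table gave, per the file headers, a mean bead intensity on a linear scale and a detection p-value for each probe and array. Its values were neither normalized between arrays nor background-subtracted. The other table, keyed by sample, gave the authors' processed intensity values on a linear scale. Its 12 columns shared 1 minimum (86.5) and 1 maximum (35095), as after quantile normalization, and no value was below 0, but the authors' method was not stated. Column medians lay between 125.8 and 125.9. GenomeStudio was named by the submitters with no version, and its settings were not stated.

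The sample names of the tables conflicted. The non-normalized columns were numbered as in the samples' description lines, but each column had the rank order of a different sample of the other table (Spearman's rho of 1 with its match, at most 0.836 with any other column). Genotype was the same under both namings for 12 of 12 columns, culture for 0 and replicate number for 0. The LIF direction of every value below therefore rests on the naming by sample accession. Under the other naming the comparisons of the deleted with the wild type cells would exchange their culture conditions. Every difference between cultures and every interaction would change sign. Replicate numbers would also join other arrays across the cultures, so every result below that uses these numbers across cultures rests on the naming too. The levels of Socs3, Klf4 and Esrrb under each naming had been seen before the table was chosen.

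The values came from the processed intensities, with a normexp background correction (offset 50), log2 and quantile normalization. The comparisons, tests, gene lists, probe filter, rule for named genes and most alternatives were fixed before the data were examined. That plan named neqc on the non-normalized intensities first, and this route for a table without control probes or detection p-values. Taking it departed from that first choice because of the naming conflict, and neqc was run as an added alternative. Detection p-values and the alternatives that use the non-normalized table followed each array by its rank order, which is a match by values and not by name. The probe filter gives the same probes under both namings, because each group keeps the same 3 arrays under another name.

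A probe was kept when its detection p was under 0.05 on all 3 arrays of at least 1 group, which left 15999 probes. Of all probes, 34885 had 1 gene symbol, 18 had several and 10378 had none listed. Gene IDs of 34807 probes matched the reference, which changed 0 symbols. Each gene was represented by its kept probe of highest mean log2 intensity, giving 9527 genes. Chromosomes were taken from the reference, and positions of the probes were not analysed here. Log2 values near the detection floor of 6.44 to 6.61 are compressed by the offset, so a fold change of a dim gene understates the difference. Where a named gene was detected on some arrays of a group, the number is given. Genes with close paralogs on the array (Gbp2 and Gbp2b, Acta1 and Actc1, Zscan4c and the Tcstv genes, Mt1 and Mt2, Tuba3a and Tuba3b) are open to cross-hybridisation.

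Raw medians of the arrays ranged from 91.2 to 216, and 32.8% to 41.8% of probes were detected per array. The number of arrays limits the precision: the median standard error of a log2 difference between groups of 3 was 0.13. In R 4.3.3, limma 3.58.1 fitted 4 group means to the 12 arrays (lmFit and eBayes, 8 residual degrees of freedom) and tested 4 pairwise contrasts and their interaction, two-sided, with Benjamini-Hochberg adjustment over the 9527 genes at 0.05. Errors of log2 fold changes are the moderated standard errors (SE) of that fit. In simulated data with known changes in 1 comparison, 6 of 50 genes changed 1.3-fold and 25 of 50 changed 1.5-fold were recovered. So were 42 of 50 changed 2-fold and 50 of 50 changed 4-fold. Of 135 calls, 12 (8.89%) were false, more than the 0.05 aimed at. The simulated noise was independent between arrays and fewer genes changed than in the data, so these shares may not carry over.

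There were 22 gene lists with 496 entries, 329 of them measured, and 9 measured genes were entered in more than 1 of the lists. They covered core and naive pluripotency, the LIF and STAT3 response, formative and primed epiblast, primitive and visceral endoderm, primitive streak and mesoderm, neuroectoderm, trophoblast, germline genes, 2-cell-like genes, DNA replication and G1/S, G2/M and mitosis, CDK inhibitors and p53 targets, HDAC1/2 complex members, other histone deacetylases, imprinted genes, genes often induced by HDAC inhibitors, REST target neuronal genes, sterol biosynthesis, fibroblast and stromal markers, the integrated stress response, hypoxia and glycolysis, and interferon-stimulated genes. Each was tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, with adjustment over the 110 list tests. Of these, 32 passed camera, 0 passed it with an estimated correlation (the lowest adjusted p was 0.101) and 39 passed fry. Set results in the text are those of camera at the preset correlation, and fry is given where the 2 disagreed. Counts of changed members use the adjustment over all genes, and those adjusted over the list alone stand beside them.

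The rule for named genes took the 10 largest rises and 10 largest falls per pairwise comparison among changed genes whose groups did not overlap (clone and predicted gene names skipped), up to 5 of each for the interaction, Hdac1 and Hdac2, and up to 4 members of each list with the largest absolute change. For genes that this rule named in a comparison and that passed and are printed, other probes were compared there. Those that did not pass, or passed with under 50% of the log2 change, are given. Genes printed outside the rule, such as Nanog and Pou5f1 for LIF removal in deleted cells, were checked neither for other probes nor in the fits without single arrays. Among all other probes of named genes the only opposing call was Rbbp4 in the deleted cells with LIF, where the gene's probe gave -0.56 without passing and another probe gave 0.54 and passed.

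Array deviations from their group mean correlated between arrays of the same number by more than 0.1 in every pair of the genotype comparisons and of the LIF comparison in deleted cells. Counts with replicate number as a block are given beside those. The alternatives were another background correction or none, neqc-type background correction together with median scaling of the arrays, the processed values as log2, no probe filter or a stricter one (detection p under 0.01), every probe, the probe of largest variance, only the arrays compared, an intensity trend, array weights, the replicate block and leaving out each array. Added after seeing the data were neqc, normexp on the non-normalized intensities with median scaling (which changes the scaling alone when set beside the same correction with quantile normalization), leaving out the 4 arrays numbered 1, and the other naming of the cultures. Median scaling aligned the arrays at the median of all probes, whereas 32.8% to 41.8% of probes were detected per array. That median lies among undetected probes, so differences in signal between arrays may remain after it. A block for the chip was not run because no chip is given.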

Results

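The arrays compared mouse ES cells that had lost Hdac1 and 1 allele of Hdac2, genes of class I histone deacetylases, with wild type cells, in medium with LIF, the cytokine that keeps mouse ES cells undifferentiated, and after 4 days without it. There were 3 arrays in each of the 4 groups: wild type with LIF, deleted with LIF, wild type without LIF and deleted without LIF. Arrays detected between 14872 and 18907 probes. Correlations of log2 values between arrays were 0.974 to 0.994 within groups and 0.929 to 0.980 between groups.

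The deleted genes themselves could be followed in part. No probe was named Hdac1. Hdac2, on chromosome 10, had 2 probes, of which 1 (ILMN_2640441) was detected on all arrays and the other was not kept. The kept probe read 11.45, 11.24 and 11.44 on the wild type arrays with LIF and 11.05, 11.25 and 11.11 on the deleted ones, a log2 fold change of -0.24 (adjusted p = 0.215, and 0.126 with replicate number as a block). Without LIF it read 11.03, 11.23 and 11.26 on the wild type and 10.85, 11.10 and 11.17 on the deleted arrays numbered 1 to 3, lower in each same-numbered pair, a difference of -0.13 (adjusted p = 0.517, and 0.412 with the block). The place of the probe relative to the removed exon is not known, so these values neither show nor exclude the deletion.

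The first comparison asked what differed between deleted and wild type cells kept in LIF. Deleted cells were taken at day 4 and wild type cells at day 0, so no value here separates the deletion from the days. Slc38a5, a glutamine transporter, rose 3.28-fold in the deleted cells (log2 fold change 1.71 ± 0.16 SE, n = 3 arrays per group, adjusted p = 0.000107). Amn, the membrane anchor of the cubilin receptor, rose 3.02-fold (1.59 ± 0.21, adjusted p = 0.000957). Fgf17, a secreted growth factor, fell by 1.74 ± 0.25 on the log2 scale (adjusted p = 0.00134), and Gdf3, a TGF-beta family ligand of pluripotent cells, fell by 1.51 ± 0.24 (adjusted p = 0.00221). Of 9527 genes, 955 changed, 635 higher and 320 lower, and 67 of them changed at least 2-fold. Groups did not overlap for 31.5% of genes, where chance gives 10%.

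Other large rises with LIF were those of Htra1, a secreted serine protease (1.47 ± 0.19), S100a6, a calcium-binding protein (1.44 ± 0.18), Cd74, the MHC class II invariant chain (1.40 ± 0.14), Taf9b, a relative of a TFIID subunit (1.38 ± 0.15), Cotl1, an actin-binding protein (1.38 ± 0.28), Nccrp1 (1.38 ± 0.21), Ddx19b, an RNA helicase (1.35 ± 0.12), and Gpx2, a glutathione peroxidase (1.35 ± 0.19). Other large falls were those of Cbr3, a carbonyl reductase (-1.30 ± 0.14), Ubap1l (-1.30 ± 0.15), Zfhx2, a zinc finger homeobox gene (-1.26 ± 0.21), Gli2, a transcription factor of hedgehog signalling (-1.25 ± 0.16), and the receptor gene Notch4 (adjusted p = 0.00163). Other probes of Taf9b (0.50) and Ddx19b (0.37) did not pass, nor did other probes of genes named below: Nr5a2 (-0.31), Wnt7b (0.41), Ndrg1 (0.52), Fbln2 (0.25), Trib3 (-0.28), Ifitm1 (-0.42, with -0.54 and a pass for a further probe), Mapk8ip1 (0.21), Hdac5 (0.34 and 0.14) and Stat3 (0.51 and 0.24).

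Among pluripotency genes with LIF, 22 were measured, 0 rose, 6 fell and 16 did not pass (0 rose and 6 fell adjusted over the list alone). Nr5a2, a nuclear receptor that acts on Pou5f1 (-0.88), Prdm14, a repressor of primed-state genes (-0.81), and Dppa3, a gene of naive cells and early germ cells (-0.81), were among those that fell. The list fell as a set (mean log2 fold change -0.36, camera adjusted p = 1.47e-05, adjusted p = 0.129 with an estimated correlation). Of 5 genes of the 2-cell-like list, 4 fell (5 adjusted over the list alone), with Tmem92 at -0.73, Zscan4c at -0.67 and Tcstv3 at -0.63, and the list fell as a set (mean -0.60, adjusted p = 9.95e-05, adjusted p = 0.218 with an estimated correlation). Of 24 genes of DNA replication and G1/S, 1 fell and 0 rose (0 adjusted over the list alone). It was Mcm3, a subunit of the replicative helicase (-0.41). That list was lower as a set (mean -0.16, adjusted p = 0.00571, adjusted p = 0.129 with an estimated correlation). In the integrated stress response list, 3 of 19 genes fell and 0 rose (8 fell and 1 rose adjusted over the list alone), among them Trib3, a pseudokinase (-0.79). The set was lower (mean -0.32, adjusted p = 0.00164, adjusted p = 0.379 with an estimated correlation and 0.121 by fry).

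Genes of several other lineages rose with LIF. Of 16 genes of primitive and visceral endoderm, 4 rose and 0 fell (7 rose adjusted over the list alone), Amn and the basement membrane collagens Col4a2 (0.74) and Col4a1 (0.71) among them (mean 0.35, adjusted p = 0.00164, adjusted p = 0.129 with an estimated correlation). Of 14 trophoblast genes, 5 rose and 0 fell (6 rose adjusted over the list alone), including the ligand gene Wnt7b (1.03), the keratin gene Krt19 (0.78) and the homeobox gene Rhox6 (0.72). That list rose as a set (mean 0.35, adjusted p = 0.0174, adjusted p = 0.379 with an estimated correlation). Of 17 germline genes, 4 rose and 0 fell (5 rose adjusted over the list alone). They included Taf7l, a germ cell paralog of a TFIID subunit (1.26 ± 0.11), and Mov10l1, a helicase of the piRNA pathway (0.76). The germline set rose (mean 0.26, adjusted p = 0.0383, adjusted p = 0.376 with an estimated correlation). Of 8 genes often induced by HDAC inhibitors, 3 rose and 0 fell (4 rose adjusted over the list alone): Crabp2, a retinoic acid-binding protein (1.03), Ndrg1 (0.81) and the metallothionein gene Mt1 (0.66). That set rose as well (mean 0.51, adjusted p = 0.0014, adjusted p = 0.284 with an estimated correlation).

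The remaining lists did not pass camera as sets in cells with LIF, although fry called the REST targets higher (adjusted p = 0.0277). Of 18 imprinted genes, 3 rose and 2 fell (3 and 2 adjusted over the list alone), with the growth factor gene Igf2 at 1.08, and Phlda2 (-0.96) and Grb10 (-0.91), which restrain growth, among the falls (set adjusted p = 0.866). Of 12 fibroblast and stromal markers, 4 rose and 0 fell (4 adjusted over the list alone), Fbln2, an extracellular matrix protein, at 1.01 (set adjusted p = 0.5). Of 11 interferon-stimulated genes, 1 rose and 2 fell (1 and 3 adjusted over the list alone), the falls being Ifitm3 (-0.82) and Ifitm1 (-0.60), which encode antiviral membrane proteins (set adjusted p = 0.459). Of 26 HDAC1/2 complex members, only Sap30, a subunit of the Sin3 complex, passed, at -0.58 (1 fell adjusted over the list alone), with a set adjusted p of 0.617. Of 13 other histone deacetylase genes, 3 rose and 0 fell (4 rose adjusted over the list alone), Hdac5 at 0.44 among them (set adjusted p = 0.263). Of 17 REST target neuronal genes 3 rose (3 adjusted over the list alone), with Mapk8ip1, a kinase scaffold, at 0.49 (set adjusted p = 0.124). Of 19 hypoxia and glycolysis genes, 1 rose (1 adjusted over the list alone), the hexokinase gene Hk1 at 0.59 (set adjusted p = 0.0991). Of 16 LIF and STAT3 response genes, 1 rose (1 adjusted over the list alone), Stat3 itself at 0.69 (set adjusted p = 0.999). Single changes in other lists were a fall of Fgf15 (-0.56) and rises of Wnt3a (0.69) and Cdkn2d, a CDK inhibitor (0.59). Adjusted over the list alone, 1 epiblast gene fell, 1 primitive streak gene rose and 1 fell, 1 neuroectoderm gene and 1 CDK inhibitor or p53 target rose, and 0 genes of the G2/M and sterol lists passed. The set adjusted p was 0.866 for formative and primed epiblast, 0.946 for primitive streak and mesoderm, 0.654 for neuroectoderm, 0.462 for G2/M and mitosis, 0.706 for CDK inhibitors and p53 targets and 0.999 for sterol biosynthesis. The median and mean had opposite signs in the LIF and STAT3, primitive streak, fibroblast and interferon lists, and camera gave the epiblast list, whose mean was 0.08, the direction down.

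With replicate number as a block, 2026 genes changed with LIF, the 955 among them. Leaving out wild type array 2 or 3 or any deleted array lowered the count, to 480, 392, 350, 468 and 411, and of the 63 named genes that passed, 40 passed without each of the 12 arrays in turn (Stat3, Col4a1, Zscan4c, Tcstv3, Mcm3, Sap30, Hdac5, Mapk8ip1, Trib3, Fgf15, Wnt3a and Cdkn2d above did not). With median scaling in place of quantile normalization on the non-normalized intensities, chosen after seeing the data, 92.3% of 313 changed genes were higher, against 66.5% here, and the calls of Gdf3, Krt19, Grb10, Ifitm1 and Ifitm3 were among those lost. Neqc-type background correction together with median scaling moved the median of all genes to 0.15, with 94.4% of 682 changed genes higher. It also ended the calls of Notch4 and Nr5a2. Such scaling aligns a median that lies among undetected probes, so differences in signal between arrays may remain and may shift the balance of calls.

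The same question was asked of cells without LIF. Taf7l rose 3.69-fold in the deleted cells (1.88 ± 0.11, n = 3 arrays per group, adjusted p = 7.29e-07). Gng13, a G protein subunit, rose 3.12-fold (1.64 ± 0.11, adjusted p = 2.56e-06), and Laptm5, a lysosomal membrane protein, rose 2.88-fold (1.52 ± 0.12, adjusted p = 9.8e-06). Car14, a carbonic anhydrase, fell by 1.73 ± 0.11 on the log2 scale (adjusted p = 1.01e-06), and was detected on 2 of 3 deleted arrays. Meis2, a developmental homeobox gene, fell by 1.61 ± 0.19 (adjusted p = 0.000256). In all 999 genes changed, 564 higher and 435 lower, 68 of them at least 2-fold. Groups did not overlap for 29.5% of genes, where chance gives 10%.

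Further rises without LIF were those of Tgm1, a transglutaminase (1.76 ± 0.16), the muscle myosin light chain genes Mylpf (1.72 ± 0.18) and Myl2 (1.56 ± 0.28, detected on 1 of 3 wild type arrays), Zbtb32, a zinc finger repressor (1.71 ± 0.25), Ddx19b (1.63 ± 0.12), the growth factor receptor gene Fgfr2 (1.58 ± 0.20) and S100a6 (1.49 ± 0.18). Further falls were those of Fgf8, a growth factor gene of the primitive streak (-1.55 ± 0.32), Gdf3 (-1.52 ± 0.24), the chemokine gene Cxcl12 (-1.34 ± 0.14), Grb10 (-1.27 ± 0.17), Phlda2 (-1.26 ± 0.13), Mid1ip1 (-1.19 ± 0.18), Epdr1 (-1.13 ± 0.17) and the cyclin D2 gene Ccnd2 (-1.11 ± 0.20). Other probes of Ddx19b (0.56) and Zbtb32 (0.48) did not pass, nor did other probes of genes named below: Stat3 (0.35, with 1.22 and a pass for a further probe), Fdps (-0.38), Ccn2 (-0.62) and Sox11 (-0.24). Further probes of Meis2 (-0.66) and Fgfr2 (0.67) passed with changes under 50% of those given on the log2 scale.

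LIF and STAT3 response genes stood higher in the deleted cells without LIF: 4 of 16 rose, 0 fell and 12 did not pass (7 rose adjusted over the list alone). Stat3 rose by 1.19, the immediate early gene Fos by 1.12, and Klf5 (0.85) and Tfcp2l1 (0.82), transcription factors downstream of LIF, rose too. The list rose as a set (mean 0.46, adjusted p = 0.000384, adjusted p = 0.129 with an estimated correlation). Among 22 pluripotency genes, 3 rose and 2 fell (3 and 3 adjusted over the list alone), the falls including Pou5f1, which encodes Oct4, at -0.87 (mean -0.06, adjusted p = 0.77). Nanog stood at -0.77 and did not pass (adjusted p = 0.0781), whereas another of its probes fell by 0.95 and passed (adjusted p = 0.00956).

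Endoderm, trophoblast, germline and HDAC inhibitor lists were again higher as sets without LIF. Of 16 endoderm genes, 3 rose and 0 fell (7 and 1 adjusted over the list alone), with Col4a2 at 0.79 and Amn at 0.85 (mean 0.31, adjusted p = 0.00127, adjusted p = 0.129 with an estimated correlation). Of 14 trophoblast genes, 6 rose and 1 fell (7 and 2 adjusted over the list alone), with Krt19 at 1.04 and Igfbp3, which binds insulin-like growth factors, at -0.92 (mean 0.32, adjusted p = 0.00496, adjusted p = 0.322 with an estimated correlation). Of 17 germline genes, 4 rose and 0 fell (5 rose adjusted over the list alone), among them Taf7l and Stag3, a meiotic cohesin subunit (0.60). The germline set rose (mean 0.29, adjusted p = 0.0121, adjusted p = 0.295 with an estimated correlation). Of 8 genes often induced by HDAC inhibitors, 3 rose and 0 fell (5 rose adjusted over the list alone), Mt1 at 1.13, Mt2 at 0.94 and Crabp2 at 0.57 (mean 0.53, adjusted p = 0.000832, adjusted p = 0.281 with an estimated correlation).

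The sets that fell without LIF included 2-cell-like genes, of which 4 of 5 fell and 0 rose (4 adjusted over the list alone), Tmem92 at -0.72 among them (mean -0.59, adjusted p = 0.000948, adjusted p = 0.272 with an estimated correlation). Of 12 sterol biosynthesis genes, 1 fell (0 adjusted over the list alone), the farnesyl diphosphate synthase gene Fdps at -0.64 (mean -0.28, adjusted p = 0.0188, adjusted p = 0.603 with an estimated correlation and 0.228 by fry). Of 19 integrated stress response genes, 3 fell and 0 rose (5 fell adjusted over the list alone), with the lipoprotein receptor gene Vldlr at -0.94 (mean -0.26, adjusted p = 0.0322, adjusted p = 0.591 with an estimated correlation and 0.175 by fry).

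The other lists did not pass camera as sets, although fry called epiblast (adjusted p = 0.00386), DNA replication (adjusted p = 0.0158) and primitive streak genes (adjusted p = 0.046) lower. Of 18 imprinted genes, 2 rose and 2 fell (2 and 2 adjusted over the list alone), Igf2 rising by 1.31 (set adjusted p = 0.529). Of 8 epiblast genes, 2 fell (2 adjusted over the list alone), Sall2, a zinc finger gene, at -1.07 (set adjusted p = 0.0593). Of 9 primitive streak genes, 2 fell (3 adjusted over the list alone), Fgf8 and Lefty1, a Nodal inhibitor, at -2.01 (set adjusted p = 0.155). Of 13 other histone deacetylase genes, 2 rose and 0 fell (2 and 1 adjusted over the list alone), Sirt7 at 0.60 (set adjusted p = 0.633). Of 12 fibroblast markers, 1 fell (2 rose and 3 fell adjusted over the list alone), Ccn2, a matrix-associated growth factor, at -0.84 (set adjusted p = 0.943). The changes in other lists were falls of the neural transcription factor gene Sox11 (-0.61), Mbd2, which binds methylated DNA (-0.71), the replication genes Mcm3 (-0.49) and Rrm1 (-0.33) and the cadherin gene Celsr3 (-0.44), and rises of Map2, a microtubule-associated protein (0.43), Prc1, a spindle midzone protein (0.35), Hk1 (0.45) and Gbp2 (1.00). Adjusted over the list alone, 1 replication gene fell, 2 neuroectoderm genes rose and 2 fell, 1 hypoxia and glycolysis gene and 2 interferon-stimulated genes rose, and 0 genes of the G2/M, CDK inhibitor and p53 target, HDAC1/2 complex and REST target lists passed. The set adjusted p was 0.106 for DNA replication, 0.716 for neuroectoderm, 0.485 for G2/M, 0.241 for CDK inhibitors and p53 targets, 0.978 for HDAC1/2 complexes, 0.706 for REST targets, 0.3 for hypoxia and glycolysis and 0.786 for interferon-stimulated genes. Median and mean had opposite signs in the HDAC1/2 complex, REST target and fibroblast lists.

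The block for replicate number gave 2084 changed genes, the 999 among them. The count fell to 442 or 400 without wild type array 2 or 3, to 491 without deleted array 3, and to 541 with the 6 arrays alone, and of 59 named genes that passed, 34 passed without each array in turn (Klf5, Amn, Igfbp3, Stag3, Crabp2, Fdps, Lefty1, Sox11, Mbd2, Mcm3, Celsr3, Map2, Prc1, Hk1 and Gbp2 above did not). Median scaling alone gave 257 changed genes, 91.1% of them higher against 56.5% here, and neqc-type background correction together with median scaling gave 307, 87.9% of them higher. Both ended the calls of Fgf8, Gdf3, Ccnd2, Pou5f1, Vldlr, Sirt7 and Ccn2, and the first those of Epdr1 and Tmem92 too, among others.

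The differences between genotypes in the 2 culture conditions were compared across genes, which are not independent replicates. The log2 fold changes correlated with a Pearson's r of 0.667 and a Spearman's rho of 0.623 over 9527 genes. Of the 425 genes that changed under both conditions, 421 changed in the same direction, 277 higher and 144 lower. If calls were independent, 52.2 were expected from the separate counts. Both comparisons use the same estimate of each gene's spread, so that expectation may be too low. Taf7l, Ddx19b, S100a6 and Igf2 were among those higher in both, and Gdf3, Grb10 and Phlda2 among those lower in both.

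**Figure D1:**
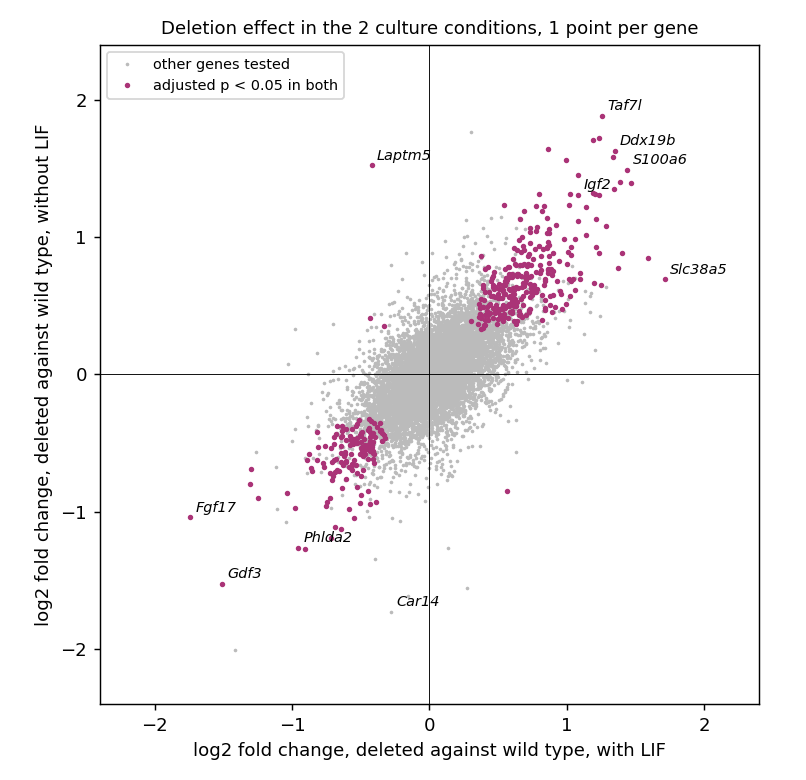
Log2 fold changes of deleted against wild type cells with LIF (horizontal) and without LIF (vertical), 1 point per gene (9527 genes). The 425 genes with an adjusted p under 0.05 in both are coloured, and 421 of them lie in the quadrants of equal sign, while Laptm5 and Car14 lie off the diagonal.

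Removal of LIF in wild type cells was the next comparison. Its direction follows the naming of the processed values, and the column names of the non-normalized table give the opposite culture for all 12 arrays. Socs3, the feedback inhibitor that STAT3 induces, fell by 3.07 ± 0.16 on the log2 scale without LIF (n = 3 arrays per group, adjusted p = 4.76e-08). The naive pluripotency factors Zfp42 (-2.56 ± 0.29, adjusted p = 4.09e-05), Esrrb (-2.55 ± 0.17, adjusted p = 2.92e-07) and Klf4 (-2.45 ± 0.22, adjusted p = 6.15e-06) fell. Kif1a, a neuronal kinesin motor, rose 6.46-fold (2.69 ± 0.12, adjusted p = 3.47e-08), and Car4, a carbonic anhydrase, rose 5.63-fold (2.49 ± 0.14, adjusted p = 7.69e-08). In all 2010 genes changed, 1054 higher and 956 lower, 261 of them at least 2-fold. Groups did not overlap for 35.0% of genes, where chance gives 10%.

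Gbp2b (2.83 ± 0.28) and Gbp2 (2.66 ± 0.24), interferon-inducible GTPases, rose, as did the muscle actin genes Acta1 (2.45 ± 0.29) and Actc1 (2.26 ± 0.27, detected on 1 of 3 arrays with LIF), the iron exporter gene Slc40a1 (2.23 ± 0.23), Ppp4r4 (2.13 ± 0.29, detected on 1 of 3 arrays with LIF), Fgf8 (2.12 ± 0.32, detected on 1 of 3 arrays with LIF) and the myosin light chain gene Myl9 (2.05 ± 0.24). Other falls were those of the homeobox gene Gbx2 (-2.74 ± 0.34), Lrrc34 (-2.29 ± 0.13), Laptm5 (-2.27 ± 0.12), the protease inhibitor gene Spink1 (-2.24 ± 0.23, detected on 1 of 3 arrays without LIF), Emp1 (-2.18 ± 0.18) and Cobl, an actin nucleator (-2.16 ± 0.15). Other probes of Cobl (-0.33), and of Dab2 (0.29, with 1.29 and a pass for a further probe) and Rrm2 (-0.14) named below, did not pass. Further probes of Gbp2 (0.50) and Actc1 (0.68), and of Peg3 (0.56) named below, passed with changes under 50% of those given on the log2 scale.

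Of 22 pluripotency genes in wild type cells, 14 fell, 1 rose and 7 did not pass (18 fell and 1 rose adjusted over the list alone). Tcl1, a co-activator of Akt kinase, fell by 2.16 and Sox2 fell by 1.05, while Pou5f1 stood at -0.36 and did not pass (adjusted p = 0.0502). The list fell as a set (mean -1.11, adjusted p = 2.12e-12, adjusted p = 0.101 with an estimated correlation). Of 16 LIF and STAT3 response genes, 9 fell and 1 rose (10 and 1 adjusted over the list alone), with Tfcp2l1 at -1.84 and the rise being that of the kinase gene Jak1 (mean -0.92, adjusted p = 1.34e-05, adjusted p = 0.129 with an estimated correlation). Of 8 epiblast genes, 5 rose and 1 fell (5 and 2 adjusted over the list alone): the transcription factor genes Otx2 (1.53) and Pou3f1 (1.38) and the DNA methyltransferase gene Dnmt3b (1.38) rose. The epiblast set rose (mean 0.67, adjusted p = 0.0322, adjusted p = 0.184 with an estimated correlation).

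**Figure D2:**
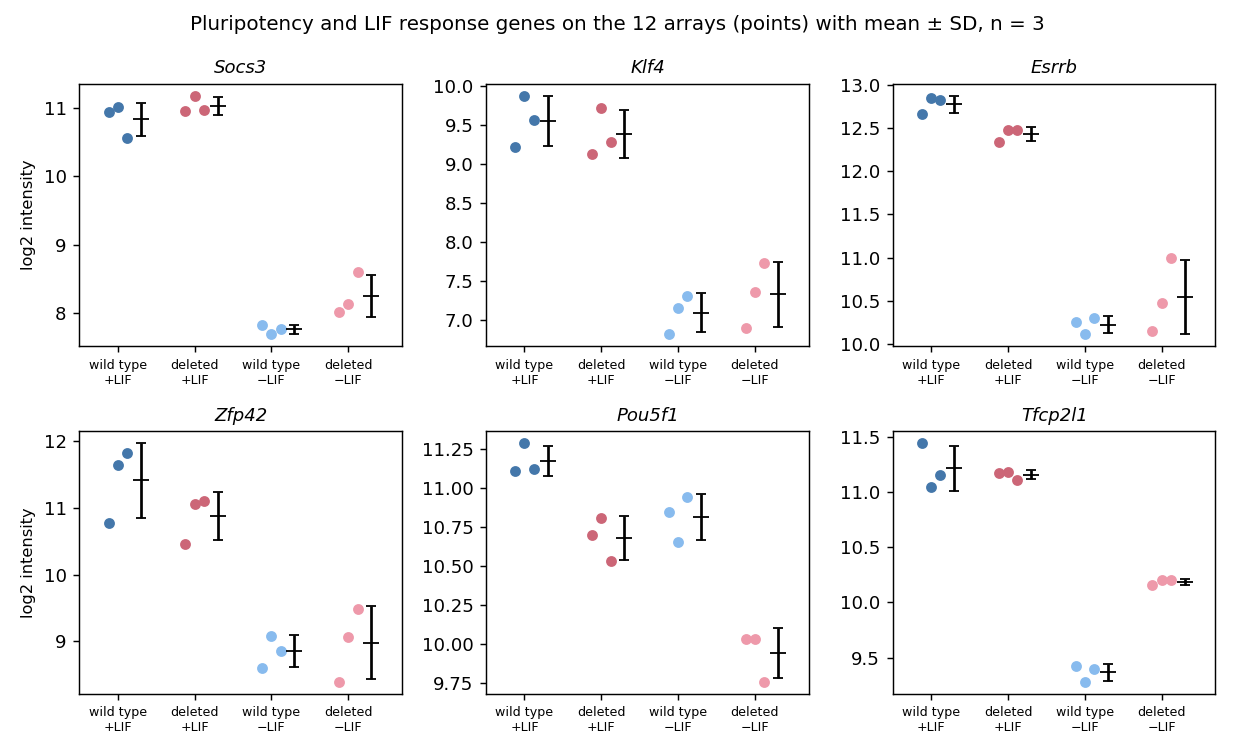
Log2 intensity of 6 pluripotency and LIF response genes on the 12 arrays, 1 point per array and group, with black bars for the mean ± SD (n = 3). Socs3, Klf4, Esrrb, Zfp42 and Tfcp2l1 lie lower on all arrays without LIF than on any with LIF in either genotype, and Pou5f1 lies lowest in the deleted cells without LIF.

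Of 17 germline genes in wild type cells, 8 fell and 0 rose (9 fell adjusted over the list alone), among them Tex14 (-1.60), which acts at germ cell bridges, Tuba3a, a testis tubulin (-1.56), and Tex19.1 (-1.23). The set fell (mean -0.57, adjusted p = 1.89e-05, adjusted p = 0.129 with an estimated correlation). Of 5 genes of the 2-cell-like list, 3 fell (5 adjusted over the list alone), Zscan4c at -0.96 (mean -0.59, adjusted p = 0.00425, adjusted p = 0.295 with an estimated correlation). Of 18 imprinted genes, 10 rose and 0 fell (11 and 1 adjusted over the list alone), with the zinc finger gene Peg3 at 1.22, Grb10 at 1.00 and Igf2 at 0.95. Imprinted genes rose as a set (mean 0.40, adjusted p = 0.00125, adjusted p = 0.129 with an estimated correlation).

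The other lists did not pass camera as sets in wild type cells, although fry called replication genes lower (adjusted p = 0.00227) and fibroblast markers (adjusted p = 0.00542), endoderm genes (adjusted p = 0.0212) and interferon-stimulated genes (adjusted p = 0.0277) higher. Of 16 endoderm genes, 5 rose and 2 fell (6 and 2 adjusted over the list alone), with the endocytic receptor gene Lrp2 at 2.01, its adaptor gene Dab2 at 1.43 and the laminin gene Lama1 at -1.96 (set adjusted p = 0.12). Of 14 trophoblast genes, 6 rose and 2 fell (6 and 3 adjusted over the list alone), Igfbp3 at 1.62 and Tfap2c at -1.21 (set adjusted p = 0.285). Of 9 primitive streak genes, 2 rose and 2 fell (2 and 2 adjusted over the list alone), Fgf8 among the rises (set adjusted p = 0.5). Of 5 neuroectoderm genes, 2 rose and 1 fell (2 and 1 adjusted over the list alone), Sox11 at 1.32 and the adhesion gene Ncam1 at -0.65 (set adjusted p = 0.47). Of 12 fibroblast markers, 4 rose and 1 fell (6 and 1 adjusted over the list alone), Ccn2 at 1.95, Acta2, smooth muscle actin, at 1.41 and the protease inhibitor gene Timp1 at -1.46 (set adjusted p = 0.126). Of 11 interferon-stimulated genes, 3 rose and 2 fell (3 and 2 adjusted over the list alone), Oasl2 at 1.47 and Ifitm2 at -0.89 (set adjusted p = 0.349). Of 24 replication genes, 5 fell and 1 rose (5 and 1 adjusted over the list alone), E2f1 at -0.90 and Rrm2, a ribonucleotide reductase subunit, at -0.65 (set adjusted p = 0.0698). Of 19 hypoxia and glycolysis genes, 4 rose and 2 fell (4 and 2 adjusted over the list alone), the phosphofructokinase gene Pfkp at -1.65 (set adjusted p = 0.241). Of 19 integrated stress response genes, 2 rose and 1 fell (2 and 1 adjusted over the list alone), Nupr1 at -1.67 (set adjusted p = 0.631). Of 26 HDAC1/2 complex members, 5 rose and 2 fell (5 and 2 adjusted over the list alone), Mbd2, which binds methylated DNA, at 0.91 (set adjusted p = 0.633). In other lists, 2 rose and 1 fell of 18 G2/M genes (2 and 0 adjusted over the list alone), 1 and 1 of 20 CDK inhibitors and p53 targets (1 and 0), 2 and 3 of 13 other histone deacetylases (3 and 3), 3 and 2 of 17 REST targets (4 and 3), 1 and 4 of 8 genes often induced by HDAC inhibitors (2 and 4), Mt2 (-0.92) among the falls, and 2 and 0 of 12 sterol biosynthesis genes (1 and 0). The set adjusted p was 0.999 for G2/M and mitosis, whose median and mean differed in sign, 0.988 for CDK inhibitors and p53 targets, 0.706 for other histone deacetylases and for REST targets, 0.443 for genes often induced by HDAC inhibitors and 0.258 for sterol biosynthesis.

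No omission of 1 array moved the wild type count by more than 1.5 times, and of 83 named genes that passed, 69 passed without each array in turn. Median scaling alone gave 717 changed genes, 31.9% of them higher against 52.4% here, and neqc-type background correction together with median scaling gave 893, 40.4% of them higher. Both ended the call of Grb10, among others.

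In the deleted cells, Socs3 fell by 2.77 ± 0.16 on the log2 scale without LIF (n = 3 arrays per group, adjusted p = 2.1e-07). Khdc3, a gene of oocytes and naive ES cells, fell too (-2.46 ± 0.14, adjusted p = 2.1e-07). Klf4 (-2.04 ± 0.22, adjusted p = 7.14e-05), Zfp42 (-1.90 ± 0.29, adjusted p = 0.0008) and Esrrb (-1.89 ± 0.17, adjusted p = 1.06e-05) fell. Gbp2b rose 11.3-fold (3.49 ± 0.28, adjusted p = 5.74e-06), Gbp2 rose 10.6-fold (3.41 ± 0.24, adjusted p = 1.36e-06) and Car4 rose 7.15-fold (2.84 ± 0.14, adjusted p = 1.23e-07). In all 1027 genes changed, 479 higher and 548 lower, 149 of them at least 2-fold. Groups did not overlap for 31.3% of genes, where chance gives 10%.

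Acta1 (2.52 ± 0.29), Lrp2 (2.22 ± 0.25), Actc1 (2.22 ± 0.27), the chemokine gene Cxcl16 (1.93 ± 0.19), Oasl2 (1.73 ± 0.23, detected on 1 of 3 arrays with LIF), the tropomyosin gene Tpm1 (1.72 ± 0.29) and Myl9 (1.68 ± 0.24) also rose in deleted cells. Spink1 (-2.25 ± 0.23), Cobl (-1.86 ± 0.15), the co-repressor gene Tle5 (-1.84 ± 0.15), Fam25c (-1.83 ± 0.16) and Urah (-1.75 ± 0.16) fell. Other probes of Cobl (-0.22), and of Dab2 (0.17), Acta2 (0.68), Rrm2 (-0.10) and Cdc20 (0.32) named below, did not pass, whereas further probes of Dab2 (0.87), Acta2 (0.68 and 1.37) and Cdc20 (0.52 and 0.56) did. Further probes of Gbp2 (0.87), Actc1 (0.58) and Cxcl16 (0.60) passed with changes under 50% of those given on the log2 scale.

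Of 22 pluripotency genes in deleted cells, 13 fell, 0 rose and 9 did not pass (16 fell and 1 rose adjusted over the list alone), with Tcl1 at -1.48, Sox2 at -0.87, Nanog at -0.88 and Pou5f1 at -0.74 (mean -0.81, adjusted p = 5.61e-11, adjusted p = 0.101 with an estimated correlation). Of 16 LIF and STAT3 response genes, 5 fell and 0 rose (5 and 1 adjusted over the list alone), Gbx2 at -1.43 and Tfcp2l1 at -0.97 (mean -0.49, adjusted p = 0.0174, adjusted p = 0.284 with an estimated correlation). Of 17 germline genes, 9 fell and 1 rose (10 and 1 adjusted over the list alone), the rise being that of Taf7l, and Tuba3a stood at -1.42 (mean -0.54, adjusted p = 5.3e-06, adjusted p = 0.129 with an estimated correlation). Of 5 genes of the 2-cell-like list, 3 fell (4 adjusted over the list alone), Zscan4c at -0.99 (mean -0.57, adjusted p = 0.00258, adjusted p = 0.284 with an estimated correlation). Of 18 imprinted genes, 8 rose and 0 fell (8 adjusted over the list alone), Peg3 at 1.46 and Igf2 at 1.18 (mean 0.42, adjusted p = 1.89e-05, adjusted p = 0.129 with an estimated correlation). Of 11 interferon-stimulated genes, 4 rose and 2 fell (4 and 2 adjusted over the list alone). The largest rises were those of Gbp2 (3.41) and Oasl2, followed by Ifitm3 (0.96) and the tetherin gene Bst2 (0.76). That set rose (mean 0.56, adjusted p = 0.0322, adjusted p = 0.272 with an estimated correlation), and Gbp2 and Oasl2 made up most of its mean.

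The other lists did not pass camera as sets in deleted cells, although fry called replication genes lower (adjusted p = 0.00951) and G2/M (adjusted p = 0.0129) and epiblast genes (adjusted p = 0.0224) higher. Of 8 epiblast genes, 4 rose and 1 fell (4 and 1 adjusted over the list alone), Pou3f1 at 0.98, Dnmt3b at 0.76 and Tcf15, a gene of early primed cells, at -1.02 (set adjusted p = 0.0891). Of 16 endoderm genes, 5 rose and 2 fell (7 and 3 adjusted over the list alone), Apoe at 1.20, Dab2 at 1.00 and Lama1 at -1.74 (set adjusted p = 0.0873). Of 14 trophoblast genes, 5 rose and 1 fell (7 and 1 adjusted over the list alone), Krt19 at 0.93 and Tfap2c at -1.09 (set adjusted p = 0.0719). Of 5 neuroectoderm genes, 3 rose and 1 fell (3 and 1 adjusted over the list alone), Sox11 at 1.06 (set adjusted p = 0.258). Of 9 primitive streak genes, 1 fell (1 adjusted over the list alone), Wnt3a at -0.93 (set adjusted p = 0.93). Of 12 fibroblast markers, 4 rose and 2 fell (4 and 3 adjusted over the list alone), Acta2 at 1.57 and Timp1 at -1.14 (set adjusted p = 0.349). Of 17 REST targets, 5 fell and 1 rose (5 and 2 adjusted over the list alone), Stmn2, a neuronal tubulin regulator, at -0.86 and the synaptic vesicle gene Syp at 0.78 (set adjusted p = 0.706). Of 19 hypoxia and glycolysis genes, 2 rose and 3 fell (4 and 3 adjusted over the list alone), Pfkp at -1.27 (set adjusted p = 0.462). The changes in other lists were falls of E2f1 (-0.77), Rrm2 (-0.55), Birc5 (-0.41), Sirt1 (-0.68) and Nupr1 (-1.19), and rises of Cdc20 (0.57), Sirt2 (0.37) and Vldlr (0.52). Adjusted over the list alone, 2 replication genes fell, 1 gene rose and 1 fell in each of the G2/M, other histone deacetylase and stress response lists, 1 gene often induced by HDAC inhibitors fell, and 0 genes of the CDK inhibitor and p53 target, HDAC1/2 complex and sterol lists passed. The set adjusted p was 0.18 for DNA replication, 0.0837 for G2/M, 0.435 for CDK inhibitors and p53 targets, 0.241 for HDAC1/2 complexes, 0.978 for other histone deacetylases, 0.438 for genes often induced by HDAC inhibitors, 0.5 for sterol biosynthesis and 0.999 for the integrated stress response. Median and mean had opposite signs in the primitive streak, REST target and stress response lists.

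**Figure D3:**
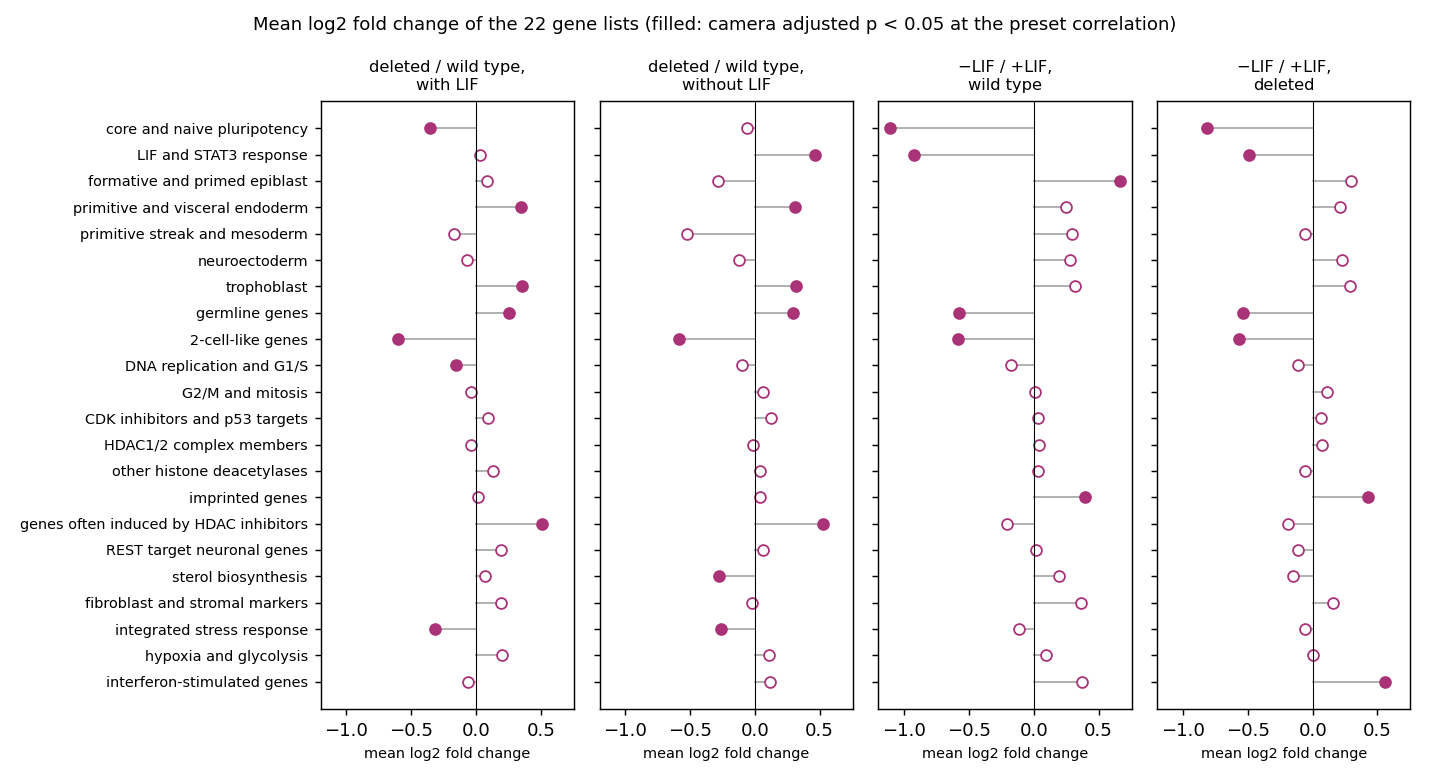
Mean log2 fold change of the measured members of the 22 gene lists in the 4 pairwise comparisons, with filled points where camera at the preset correlation gave an adjusted p under 0.05. The pluripotency list lies at -1.11 and -0.81 without LIF in wild type and deleted cells, and the list of genes often induced by HDAC inhibitors lies at 0.51 and 0.53 in the deleted cells with and without LIF.

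The block for replicate number gave 1849 changed genes in deleted cells, the 1027 among them. The count fell to 573, 568 or 652 without deleted array 1, 2 or 3 with LIF and to 659 without deleted array 2 without LIF, and of 69 named genes that passed, 54 passed without each array in turn (Gbx2, Birc5, Sirt1, Sirt2 and Vldlr above did not). Median scaling alone gave 362 changed genes, 69 of them higher and 293 lower, against 46.6% higher here. Neqc-type background correction together with median scaling moved the median of all genes to -0.19, with 603 changed genes, 18.1% of them higher. Both ended the calls of Pou3f1, Dnmt3b, Ifitm3, Krt19 and Sox11, and the first those of Tpm1 and Stmn2 too, among others. Across genes, the LIF effects in wild type and deleted cells correlated with a Pearson's r of 0.797 and a Spearman's rho of 0.698. Of 790 genes that changed in both, 788 changed in the same direction. If calls were independent, 108 were expected, which may be too low because both comparisons use the same estimate of each gene's spread.

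The interaction asked which genes differed between genotypes by another amount without LIF than with it. Its signs depend on the same naming of the cultures. It passed for 5 genes, 2 positive and 3 negative. Laptm5 (probe ILMN_1217849, chromosome 4) had 1.94 ± 0.17 on the log2 scale (adjusted p = 0.000217): it fell by 2.27 without LIF in wild type cells and stood at -0.32 in deleted cells. Car14 (ILMN_2973824, chromosome 3) had -1.44 ± 0.15 (adjusted p = 0.000796), with 1.65 in wild type and 0.20 in deleted cells, and was detected on 1 of 3 deleted arrays with LIF. Tgm1 (chromosome 14) had 1.46 ± 0.23, Ccn2 (chromosome 10) had -1.41 ± 0.23, and Npw, a neuropeptide gene (chromosome 17), had -1.05 ± 0.16, each with an adjusted p of 0.0452, and Npw was detected on 1 of 3 wild type arrays with LIF. Another probe of Ccn2 gave -1.07 and did not pass. Npw and Car14 each had a group mean near the detection floor, and under neqc their interactions were -1.90 and -2.10.

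**Figure D4:**
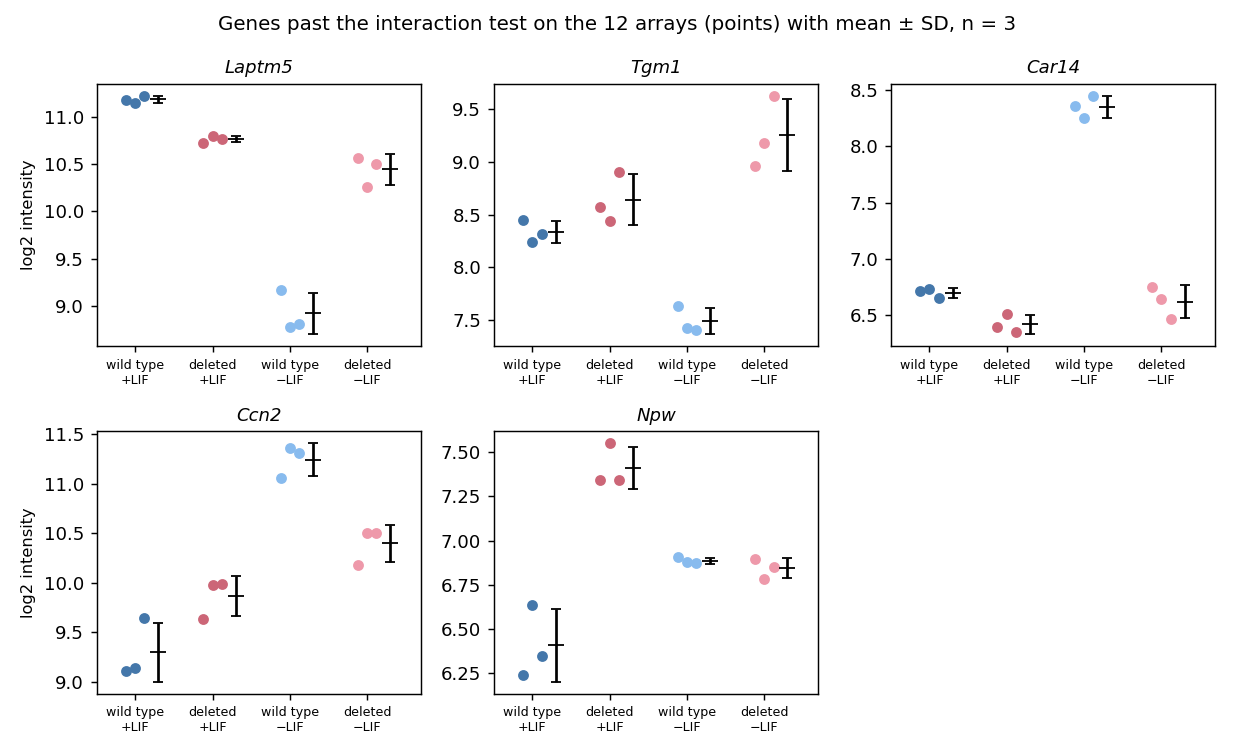
Log2 intensity of the 5 genes past the interaction test on the 12 arrays, 1 point per array, with black bars for the mean ± SD (n = 3). Laptm5 lies at a mean of 8.92 in wild type cells without LIF and above 10 in the other groups, and Car14 lies at 8.35 in wild type cells without LIF and below 7 in the others.

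Among the lists, 0 of 22 pluripotency genes passed the interaction (4 positive adjusted over the list alone), yet the list was positive as a set (mean 0.30, adjusted p = 5.3e-06, adjusted p = 0.129 with an estimated correlation). The LIF and STAT3 list was positive as well, with 0 of 16 genes past the test and 3 adjusted over the list alone (mean 0.43, adjusted p = 5.3e-06, adjusted p = 0.129 with an estimated correlation). Klf4, Klf5 and Tfcp2l1 are members of both lists, so these set results are not independent. Negative sets were formative and primed epiblast, with 0 of 8 genes and 3 adjusted over the list alone (mean -0.37, adjusted p = 0.031, adjusted p = 0.184 with an estimated correlation), and sterol biosynthesis, with 0 of 12 genes and 0 adjusted over the list alone (mean -0.35, adjusted p = 0.00694, adjusted p = 0.528 with an estimated correlation and 0.332 by fry). The other lists passed neither camera nor fry, G2/M and mitosis having the lowest camera adjusted p among them (0.0514), and 1 fibroblast marker, Ccn2, passed singly. Adjusted over the list alone, 1 HDAC1/2 complex member, 1 germline gene, 1 interferon-stimulated gene and 2 genes often induced by HDAC inhibitors were positive, and 1 of the latter, 1 primitive streak gene and 1 fibroblast marker were negative. Median, mean and test differed in sign in the neuroectoderm, endoderm, trophoblast, germline, 2-cell-like, HDAC inhibitor and integrated stress response lists, none of which passed.

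The block for replicate number gave 13 genes. The count lay between 2 and 9 when arrays were left out in turn, only Laptm5 and Car14 passing each time, Tgm1 and Ccn2 did not pass under neqc, and with median scaling, alone or with neqc-type background correction, 1 gene passed, Laptm5. The share of positive calls, 40% here, was 100% of that 1 gene, 28.6% of 7 genes with the stricter probe filter, 25% of 4 genes with neqc and 33.3% to 66.7% of 2 to 9 genes when single arrays were left out.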

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

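The tests of the culture labels and of the brightness of the arrays numbered 1, and the regrouping within replicate numbers, were chosen only after the results were seen. Single genes and lists stood out because the difference between genotypes was not the same with and without LIF. The log2 interactions were 1.94 for Laptm5, -1.44 for Car14, 1.46 for Tgm1, -1.41 for Ccn2 and -1.05 for Npw. Those of Car14 and Npw involve a group near the detection floor and were -2.10 and -1.90 under neqc. The mean interactions of lists were 0.298 for pluripotency, 0.429 for LIF and STAT3 response, -0.367 for formative and primed epiblast and -0.353 for sterol biosynthesis. No list interaction passed camera with an estimated correlation, and that of sterol biosynthesis did not pass fry. Among 100 regroupings of the 12 arrays after genotype and LIF effects were taken out, only the real one (1) gave 5 genes, the highest other giving 1 gene. Taking these effects out shrinks regroupings that resemble them but not the real one, so this share may be too low. Of 10 splits of the 6 arrays of each pairwise comparison, only the real one (1) reached its count and the highest other gave 0 genes. Every other split joined arrays of both real groups, so the real difference widened the spread within its groups. These 0 counts are therefore no measure of chance, and 10 splits are too few to exclude it.

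The pluripotency list fell less without LIF in deleted cells (-0.81) than in wild type cells (-1.11), with 17 of 22 members positive in the interaction and 0 past the test. Of 100 regroupings of all 12 arrays, 8 gave a mean as large, up to 0.421. Of 100 that kept 1 array of each number in each group, only the real one (1) did, the highest other giving 0.280. Taking out the genotype and LIF effects shrinks regroupings that resemble them but not the real one. Both shares can therefore be too low, and chance is not excluded. Over the 20 members detected on all arrays the mean was 0.312. Most of the 22 members stayed in, and detection does not remove compression near the floor, so this cannot decide on compression of dim probes. Without the arrays numbered 1 the mean was 0.333, which argues against unequal deviations of these arrays as its source. A deviation that they share equally cancels in the interaction, since each group holds 1 of them, so this was no test of it. The list stood lower in deleted cells with LIF (mean -0.36), whereas without LIF its mean was -0.06 with 3 members higher and 2 lower, and the cause is open.

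The culture labels of the 2 tables conflict, and the LIF response genes speak to it. Called members of that list were lower without LIF 14 times and higher 1 time over both genotypes, which argues against swapped labels in the processed values. Columns of the non-normalized table matched the array of their own name 0 times of 12, which is the conflict itself and does not tell which table is misnamed. Socs3, Klf4 and Esrrb had been seen before the table was chosen, and the 14 lower calls include Socs3 and Klf4, so this test is not independent of that choice.

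The 4 arrays numbered 1 deviated from their groups in the same way (pairwise r of 0.449 to 0.681). In the 12 arrays 2417 genes differed between number 1 and the others, Egr1 (-1.69) and Dusp6 (-1.18) among the lower and Gadd45g (1.63) among the higher. Brightness was argued against: number 1 was the dimmest array in 2 groups and the brightest in 1. The lowest correlation stayed at 0.389 under neqc, so a shared culture, preparation or run may be the cause, which no label can tell. Sterol biosynthesis (mean 0.367, adjusted p = 4.22e-05), genes often induced by HDAC inhibitors (0.304, 0.00416) and CDK inhibitors and p53 targets (0.179, 0.00755) stood higher on these arrays, and the integrated stress response (-0.223, 0.00359) and pluripotency (-0.219, 0.00921) lower, 0 of them with an estimated correlation (lowest adjusted p = 0.203), and no biological explanation was tested.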

How the results depend on the processing

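No named gene or list call reversed except under the other culture naming, which turned every LIF and interaction direction and exchanged the genotype counts of the cultures. Of 279 calls of named genes, 279 stayed with normexp on the non-normalized intensities and with a replicate block, 250 with neqc and 243 without a probe filter. Neqc-type background correction together with median scaling (both, below) kept 194, and normexp with median scaling (scaling alone, below) kept 176. These 2 settings align a median that lies among undetected probes, so differences in signal between arrays may remain in them. Calls were also gained among the 414 named gene values. The block added 92 in the same direction, array weights 76 and the omission of the arrays numbered 1 added 61. A named gene that did not pass is therefore not shown to be unchanged. The balance of calls turned in wild type cells, from 52.4% higher without LIF to 31.9% with scaling alone and 40.4% with both, and in the interaction, from 40% positive to 100% of 1 gene with either, 60% of 5 without wild type array 1 with LIF and 66.7% of 3 without deleted array 3 with LIF. All 32 list calls stayed with the block, 28 with array weights, 29 with neqc and 0 with an estimated correlation. Some lists that did not pass here passed under other settings. The epiblast fall in deleted cells without LIF did so under 8 of 28, and the positive G2/M interaction under 8 of 27. The trophoblast rise without LIF in deleted cells did so under 7 of 28. The epiblast interaction ended under 10 of 27 settings, the germline rise with LIF under 7 of 28, the sterol interaction under 6 of 27, the epiblast rise in wild type cells and the LIF and STAT3 fall in deleted cells under 5 of 28 each, and the trophoblast rise with LIF, the stress response and sterol falls in deleted cells without LIF and the interferon rise without LIF in deleted cells under 4 of 28 each. Deleted and wild type cells differed in 955 genes with LIF, against 313 with scaling alone, 534 without the filter, 1882 with array weights, 2026 with the block, 1540 without the arrays numbered 1, and 350 to 1190 without single arrays (wild type 2 480, wild type 3 392, deleted 1 350, deleted 2 468, deleted 3 411). Without LIF they differed in 999, against 257 with scaling alone, 307 with both, 595 without the filter, 541 with 6 arrays, 2705 with weights, 2084 with the block, and 400 to 1172 without single arrays (wild type 2 442, wild type 3 400, deleted 3 491). Between cultures 2010 differed in wild type cells, against 717 with scaling alone, 893 with both, 3275 with weights, 3021 with the block and 1350 to 2228 without single arrays. In deleted cells 1027 did, against 362, 603, 1842, 1849 and 568 to 1137 (with LIF 1 573, 2 568, 3 652; without LIF 2 659). The interaction passed for 5 genes, against 9 without background correction, 1 with scaling alone or both, 8 with processed log2 values, 3 probes, 87 with weights, 13 with the block, 15 without the arrays numbered 1 and 2 to 9 without single arrays (wild type with LIF 2 3, 3 3; deleted with LIF 1 2, 2 2, 3 3; wild type without LIF 1 9, 2 2, 3 2; deleted without LIF 2 2, 3 2). The correlation of genotype differences between cultures was 0.667, against 0.629 with both, 0.521 without the filter, 0.627 with neqc and 0.561 to 0.685 without single arrays (wild type with LIF 2 0.617, wild type without LIF 2 0.607, deleted without LIF 1 0.561). Fewer arrays lower the power by construction, and an absent filter adds undetected probes. Otherwise the cause was not tested. Neqc, the scaling alone, the omission of the arrays numbered 1 and the other culture naming were chosen after seeing the data. Signal over background limits dim genes: between 32.8% and 41.8% of probes were detected per array. A chip block was not run, since no chip is given.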

Other observations

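X-linked genes stood out among the genes that rose without LIF. The tests in wild type cells and between genotypes, the correlation of the mean differences and the tests of the projection below were chosen only after the result was seen, whereas the test in deleted cells was written before it was run. In wild type cells 69 of 319 X-linked genes rose (21.6%) against 985 of 9200 others (10.7%), an odds ratio of 2.30 (Fisher's exact adjusted p = 2.38e-07). In deleted cells, on other arrays, 39 of 319 rose (12.2%) against 440 of 9200 (4.78%), an odds ratio of 2.77 (adjusted p = 1.03e-06). LIF effects of the 2 genotypes correlated across genes (Pearson's r of 0.797) and shared 1 estimate of the spread. The result in deleted cells is therefore not independent of that in wild type cells. Among the rises in deleted cells with LIF, 22 of 319 X-linked genes and 612 of 9200 others gave an odds ratio of 1.04 (Fisher's exact p = 0.819). In all, 32 X-linked genes rose in both genotypes, among them Lpar4 (2.04 and 1.23), Flna, an actin crosslinker (0.93 and 0.88), Plp2 (0.92 and 0.82), Rlim, a ubiquitin ligase (0.87 and 0.61), and Fgf13 (0.87 and 0.79). Genes are not independent, the line is male per the labels, and no cause was tested.

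The mean differences by genotype and by LIF removal were not correlated across genes, although genes such as Igf2 and Grb10 changed under both. They gave a Pearson's r of -0.00476 and a Spearman's rho of 0.0173 over 9527 genes. Averaged over both cultures, the genotype difference thus did not run in the direction of LIF removal. Opposite differences in the 2 cultures would cancel in that average, so it cannot decide the question for either culture alone. The difference of each pair of same-numbered arrays was projected on the mean LIF effect of the pairs with other numbers. The projections were 0.973 ± 0.093 SD in wild type and 0.784 ± 0.067 SD in deleted cells (n = 3 each), a difference of -0.189. Every deleted pair lay below every wild type pair, and within numbers 1, 2 and 3 the differences were -0.128, -0.237 and -0.201. The exact permutation p of 0.1 between groups and the exact sign-flip p of 0.25 within numbers are the smallest that 3 values allow, so a smaller LIF response in deleted cells stays open. The pairs of same-numbered arrays and the directions of these LIF values rest on the naming of the processed values.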
